A study of Homo sapiens with 6 samples.

How the data were processed

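RNA was measured on 6 Illumina human BeadChip arrays from melanoma tumour-infiltrating lymphocytes, 3 lines sorted into a CD28+ and a CD28- subset each. Per the labels, RNA was extracted with Trizol and cleaned on RNeasy columns, or with RNeasy alone per the design text, and biotin-labelled cRNA was hybridised. The deposited table gives for each probe and array the mean bead signal as an intensity on a linear scale, with no background subtracted and no normalization between arrays, and a detection p-value against the negative control beads, per the file headers. BeadStudio made these values, per the submitters' processing notes, and its version is not given in the sources used here. The authors' deposited value table of the same arrays holds intensities that, from the values, had been background-subtracted (between 33.9% and 34.0% of them lie below 0) and quantile normalized. Within each array these rank as the unnormalized signals do (rank correlation 1), and their medians lie between 6.27 and 6.31. They were used as an alternative only. The steps behind them are not stated in words. No file gives a slide or scan batch.

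The table held 48804 rows for 48803 probes; the probe listed again was averaged. Probes were named through their RefSeq accession in a gene table of assembly GRCh38.p14, used for names and neighbours only: 25277 accessions matched. Otherwise the symbol of the file was kept (9630 probes) or replaced where it was an older name of 1 current gene (1059 probes). 12837 probes had no symbol. XIST and Y-linked genes (145 probes) were left out of every step. For the main values the background was corrected by the normexp model with control parameters inferred from the detection p-values, an offset of 16 was added, arrays were quantile normalized, and log2 was taken (limma 3.58.1 in R 4.3.3). Probes detected at p under 0.01 on at least 3 of the 6 arrays, whatever their group, were tested: 11825 probes, of which 233 had no symbol, standing for 9222 genes. Array pairs correlated between 0.957 and 0.984, and no 2 arrays held identical values. A gene was represented by its brightest tested probe, and other probes of a named gene are given where they differ in the call.

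Each probe was fitted with limma (lmFit and eBayes), the TIL line as a fixed block and the subset as the effect; tests were two-sided with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The block follows from the design text, by which each culture was sorted into both subsets, and from the line numbers in the titles. As a check, the deviations from the group means of the 2 arrays of a line correlated between 0.455 and 0.660, whereas arrays of different lines reached at most -0.0608, values that centring pushes below 0. The residual degrees of freedom were 2, and the prior added 8.11. Where a probe was not detected on any array of one group, its change is given as a bound. The bright group's mean was then set against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

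Gene lists fixed before the data were examined were tested with camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry, on lists with at least 3 measured genes. There were 32 lists with 574 genes, 58 of which are in 2 or more lists. They covered memory and less differentiated T cells, cytotoxic effectors, natural killer type receptors, inhibitory receptors and exhaustion, costimulation, cytokine receptors, cytokines, chemokines, chemokine receptors and adhesion, type 17 and type 2 programs, transcription factors, cell cycle, apoptosis, senescence and telomeres, T cell receptor signalling, glycolysis, oxidative phosphorylation, interferon response, HLA class II, immediate early and stress genes, ribosomal proteins, and markers of CD8, CD4 and regulatory, and gamma-delta T cells, natural killer cells, B and plasma cells, monocytes and macrophages, dendritic cells, melanocytes, fibroblasts and endothelium, and erythrocytes and platelets. CD28 and CD4 were left out of them. The genes named in the text follow a rule set at the same time: the sort markers CD28, CD4, CD8A and CD8B, the 12 largest log2 differences in each direction among genes past the threshold that moved the same way in all 3 lines, and in each list up to 4 members of smallest p and any member past the threshold. Hypothetical genes, receptor segments and pseudogenes were passed over. KIR and HLA genes, whose presence or sequence differs between people, are given as group values only. The list counts include 1 gene past the threshold whose own values are not reported here.

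The procedure was tested on simulated data for this comparison, with 200 of 11825 probes changed and 10 simulations. With spreads drawn from the fitted prior, 14.2% of changes of 0.5, 94.9% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 5.12% of calls were false. With each probe's own moderated spread, 44.3%, 99.9% and 100% were recovered and 8.96% of calls were false. A list of 20 genes shifted by 0.5 was called in 10 of 10 simulations, and other lists in 1 of 190 tests. The simulated noise was independent between probes and the lists were random. These counts therefore do not show how often lists of correlated genes are called wrongly, and the estimated correlation of the chemokine list was 0.652. Alternatives were no block, the line as a random block, no background correction, an offset of 50, median scaling, cyclic loess, the authors' values, other detection filters, an intensity trend with a robust prior, array weights, leaving out each line or array, other list tests and the mean over the probes of a gene. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.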

Results

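Gene expression was measured in human melanoma tumour-infiltrating lymphocytes (TIL), the T cells that grow out of tumour fragments kept in culture with interleukin-2. Per the labels, each of 3 TIL lines was grown out, expanded with an anti-CD3 antibody, irradiated feeder blood cells and interleukin-2, stained for CD4 and CD28, and sorted into a CD28+ and a CD28- subset, which rested for some hours before RNA was taken. The sample titles call the sorted cells CD8+, whereas the design text describes a gate on cells without CD4. CD28 is the main costimulatory receptor of T cells, and its loss accompanies repeated stimulation and late differentiation. The comparison asks how the 2 subsets of the same culture differ in expression. There were 6 Illumina BeadChip arrays, 1 per subset and line, so 3 per group. The median deposited signal of an array lay between 82.0 and 91.4, and between 11246 and 12606 of the 48803 probes were detected above the negative controls (detection p under 0.01). Values below are normalized log2 signals, differences are CD28+ minus CD28-, and group values are means ± SD with n = 3 arrays. The number of arrays limits the precision. Each line was sorted once, so limma p-values rest on the spread between these 3 pairs of samples only, moderated by that of all probes. The camera p-values instead set the genes of a list against the other genes. At the preset correlation of 0.01 they treat genes as nearly independent, so their size does not measure the spread between pairs.

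The sort marker behaved according to the labels. CD28 (probe ILMN_1749362) had a signal of 8.34 ± 0.13 (SD, n = 3) in CD28+ cells and was not detected on any CD28- array (5.12 ± 0.38), which makes it at least 4.57-fold higher in CD28+ (limma, Benjamini-Hochberg adjusted p = 6.93e-06, higher in 3 of 3 lines). CD4 was not detected on any of the 6 arrays. CD8A differed by -0.08 (SE 0.13, limma adjusted p = 0.819) and CD8B by 0.12 (SE 0.13, limma adjusted p = 0.689), neither larger than the spread between the pairs. CD3D, a chain of the T cell receptor complex, differed by -0.23 (limma adjusted p = 0.422). CD28 is a check of the labels and not a finding, and it was kept out of the gene lists together with CD4.

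CD28- cells carried more RNA of several receptors otherwise typical of natural killer cells, among them KLRC2 and NCAM1, of the chemokine receptor CXCR6 and of the hair keratin KRT86. CD28+ cells carried more RNA of the IgE receptor FCER2, the lymph-node homing receptor CCR7 and the interleukin-7 receptor chain IL7R. FCER2 (probe ILMN_1662451) showed the largest rise apart from CD28, from 7.15 ± 0.13 in CD28- to 9.63 ± 0.64 in CD28+, a log2 difference of 2.48 (SE 0.21, limma adjusted p = 0.000195). KLRC2, an activating receptor for HLA-E, showed the largest fall, from 10.28 ± 1.26 to 6.72 ± 0.64, a log2 difference of -3.56 (SE 0.48, limma adjusted p = 0.00292). KRT86 (probe ILMN_2178226) fell from 9.67 ± 0.40 to 6.62 ± 0.58 (log2 difference -3.05, SE 0.14, limma adjusted p = 6.93e-06). CXCR6, the receptor for CXCL16, fell from 9.79 ± 0.21 to 7.08 ± 1.11 (log2 difference -2.71, SE 0.27, limma adjusted p = 0.000478). All of these moved the same way in 3 of 3 lines. KLRC2 and KRT86 were detected on 2 of the 3 CD28+ arrays.

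Of 11825 probes tested with the line as a block, 476 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 249 of them higher and 227 lower in CD28+ cells. They stood for 369 named genes, 186 higher and 183 lower. All 476 moved in one direction in all 3 lines, which a paired test at this threshold itself favours and which is no separate support. Of them, 134 changed more than 2-fold, 64 upward and 70 downward. Without the block, which sets the 2 groups of 3 arrays against each other unpaired, 10 probes passed (3 higher, 7 lower), CD28, FCER2, KRT86, SPINK2, CCR1 and RSAD2 among them. With the line as a random block 245 passed. Leaving out line 1 gave 608 probes, leaving out line 2 255 and leaving out line 3 265. The 608 is no sign of stronger calls. Without line 1 the SE of CD28 was 0.208, against 0.154 with all lines, yet its limma adjusted p was 1.22e-47 against 6.93e-06. The p-values of that fit are therefore not comparable with the others. With single arrays left out and the line as a random block, the counts were 148 and 150 without the CD28+ or CD28- array of line 1, 171 and 166 for line 2, and 34 and 15 for line 3.

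**Figure D1:**
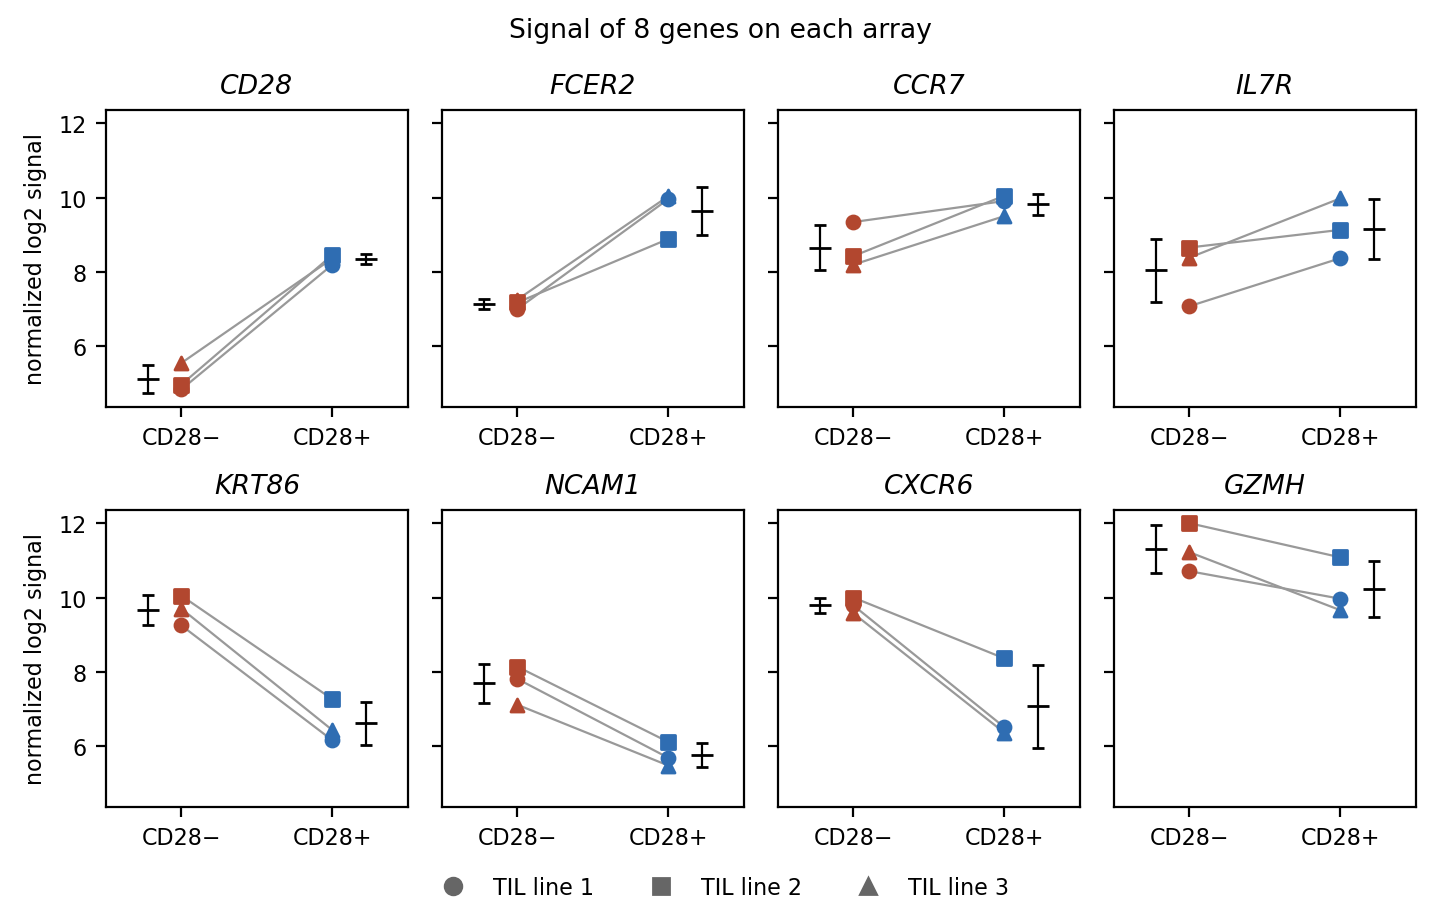
Normalized log2 signal (vertical axis) of 8 genes on each of the 6 arrays, by sorted subset (horizontal axis). Symbols are TIL lines, grey lines join the 2 subsets of a line, and the black bars beside them give the mean ± SD of 3 arrays. CD28, FCER2, CCR7 and IL7R are higher in the CD28+ subset of 3 of 3 lines, and KRT86, NCAM1, CXCR6 and GZMH are lower in 3 of 3. At a detection p under 0.01, CD28 was not detected in CD28- cells, nor NCAM1 in CD28+ cells. The detection p of NCAM1 on the CD28+ arrays lay between 0.0105 and 0.0264. That of CD28 on the CD28- array of line 3 was 0.025.

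The other genes with the largest rises in CD28+ cells were BEX2 (log2 difference 1.70), HSF4 (1.58), PRSS57 (1.56), OLAH (1.54), TMOD1 (1.51), IER3 (1.51), CD248 (1.46), EEF1A2 (1.43), RAB11FIP5 (1.43), DRC9 (1.43) and CPVL (1.39). They include HSF4, a heat shock transcription factor, TMOD1, which caps actin filaments, and OLAH, a thioesterase of fatty acid synthesis. Their limma adjusted p-values ran from 0.000174 for BEX2 to 0.0447 for EEF1A2. BEX2, CD248 and RAB11FIP5 were detected on 1 of the 3 CD28- arrays. SPINK2, a serine protease inhibitor, was not detected on any CD28+ array and was at least 3.37-fold lower there (limma adjusted p = 8.68e-05). Members of the killer cell immunoglobulin-like receptor (KIR) family, which bind HLA class I, were among the genes with the largest falls. KIR2DL4 (-2.21) and KIR2DL3 (-2.28) were detected on all arrays. The fitted differences of KIR2DS5 (-2.58), KIR3DL2 (-2.55, SE 0.18, limma adjusted p = 8.68e-05), KIR3DL1 (-2.41), KIR2DL5A (-2.39) and KIR3DL3 (-2.37) are less certain in size, as each was detected on only 1 or 2 of the 3 CD28+ arrays. KIR2DL2 was not detected on any of these and was at least 4.41-fold lower there. KIR genes resemble each other closely, so single members are uncertain.

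Natural killer type receptors were lower in CD28+ cells as a group. Of 17 measured members of this list, 9 fell, none rose and 8 did not pass. Adjusted over the list alone, 11 fell. The list median was -1.56 (-1.53 with NCAM1 at its bound), below 0 in all 3 lines, and the list was shifted downward against other genes (camera adjusted p = 8.29e-16; adjusted p = 0.379 with an estimated correlation). Outside the KIR family, KLRC1, an inhibitory receptor for HLA-E, detected on 1 of the 3 CD28+ arrays, fell by 1.56 on the log2 scale (SE 0.14, limma adjusted p = 0.000315), and CD244, a receptor for CD48, by 0.68 (SE 0.16, limma adjusted p = 0.0404). NCAM1, the CD56 antigen, was not detected on any CD28+ array and was at least 2.88-fold lower there (limma adjusted p = 8.68e-05). Without its KIR members, a version chosen after the data were seen, the list still passed (camera adjusted p = 5.53e-07).

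Cytotoxic effector genes were also lower in CD28+ cells. Of 19 measured, 5 fell, none rose and 14 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 6.54e-09; adjusted p = 0.379 with an estimated correlation). The 5 were FGFBP2, a secreted protein of cytotoxic lymphocytes, at -1.32 (SE 0.24, limma adjusted p = 0.0140), the granzyme GZMH at -1.07 (SE 0.17, limma adjusted p = 0.00602), the death ligands FASLG at -0.97 and TNFSF10 at -0.70, and the granule protein NKG7 at -0.56. The median of the list was -0.49 and lay below 0 in all 3 lines.

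Secreted signals followed a mixed pattern. Of 6 measured chemokines, 4 fell (CCL3 at -1.26, CCL3L1 at -1.66, CCL3L3 at -1.73 and CCL4L1 at -1.94) and CXCL8 rose (0.87, limma adjusted p = 0.0133). CCL3L1 was detected on 1 of the 3 CD28+ arrays, so its difference is less certain in size. Adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 6.69e-05; adjusted p = 0.430 with an estimated correlation). CCL3L1, CCL3L3 and CCL4L1 are near-identical copies of CCL3 and CCL4, which an array cannot separate well, and with the copies left out, as tried after the data were seen, the list did not pass (camera adjusted p = 0.347). Of 8 measured cytokines, TNF (-0.64, limma adjusted p = 0.0306), CSF2 (-0.87, limma adjusted p = 0.00756) and IL16 (-0.71, limma adjusted p = 0.0263) fell. A further tested probe of IL16 differed by -0.03. Adjusted over the list alone, 4 cytokines fell and 2 rose (camera adjusted p = 0.0352; adjusted p = 0.425 with an estimated correlation; adjusted p = 0.0849 without the replicate block).

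Chemokine receptors and adhesion molecules split by receptor. Of 23 measured, 2 rose and 6 fell, the same counts as when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0512), though it did in 4 of 21 other settings of the fit. CCR7, which guides T cells into lymph nodes, rose by 1.16 (SE 0.19, limma adjusted p = 0.00719), and S1PR1, which guides them out again, by 1.14 (SE 0.12, limma adjusted p = 0.000797). The receptors of inflammatory chemokines CCR2 (-1.70, SE 0.13, limma adjusted p = 9.91e-05), CCR1 (-1.41, SE 0.14, limma adjusted p = 0.000551) and CXCR3 (-0.70) were among those that fell, together with CXCR6 and the collagen-binding integrin chain ITGA1 (-1.12). CCR2, CCR1 and ITGA1 were each detected on 2 of the 3 CD28+ arrays, so their differences are less certain in size.

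Among 15 measured genes of memory and less differentiated T cells, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.0964, with a pass in 3 of 21 other settings). Besides CCR7 and S1PR1 these were IL7R, the interleukin-7 receptor chain (1.12, SE 0.19, limma adjusted p = 0.0106), and KLF2, a transcription factor of quiescent and recirculating T cells (0.58, limma adjusted p = 0.0420). BACH2, a repressor of effector differentiation, fell (-0.86, limma adjusted p = 0.00428), as did CXCR3. The size is less certain for BACH2, which was detected on 1 of the 3 CD28+ arrays. Of 18 transcription factors of effector and memory cells, 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.594). HOPX (-1.06), ZNF683 (-0.96) and ID2 (-0.68), all known from effector or tissue-resident lymphocytes, fell along with BACH2. ZEB2 (0.91), MYB (0.67) and MYC (0.62) rose, although the other tested probe of MYC, at 0.46, did not pass.

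Cell cycle genes were higher in CD28+ cells. Of 38 measured, 4 rose, none fell and 34 did not pass, and 14 rose when adjusted over the list alone. The list median was 0.31, above 0 in 3 of 3 lines (camera adjusted p = 6.49e-10; adjusted p = 0.425 with an estimated correlation). The 4 act in mitosis: CDC20 (0.74, limma adjusted p = 0.0204), KIF20A (0.68, limma adjusted p = 0.0357), AURKA (0.62, limma adjusted p = 0.0299) and CENPE (0.60, limma adjusted p = 0.0254). A further probe of AURKA (0.60) and one of CENPE (0.46) did not pass.

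Immediate early and stress genes, fixed as a sign of sample handling, were higher in CD28+ cells too. Of 20 measured, 8 rose and 1 fell, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.84e-08; adjusted p = 0.425 with an estimated correlation). IER3 rose by 1.51 (SE 0.16, limma adjusted p = 0.000681), FOSB by 1.13 (SE 0.17, limma adjusted p = 0.00474), DUSP1 by 0.99, ATF3 by 0.94, FOS by 0.90, EGR1 by 0.74, JUNB by 0.69 and the heat shock gene HSPA1B by 0.69, whereas EGR3 fell (-0.66, limma adjusted p = 0.0236). The anti-CD28 antibody of the sort bound the CD28+ cells alone, so this difference cannot be separated from the staining by design.

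**Figure D2:**
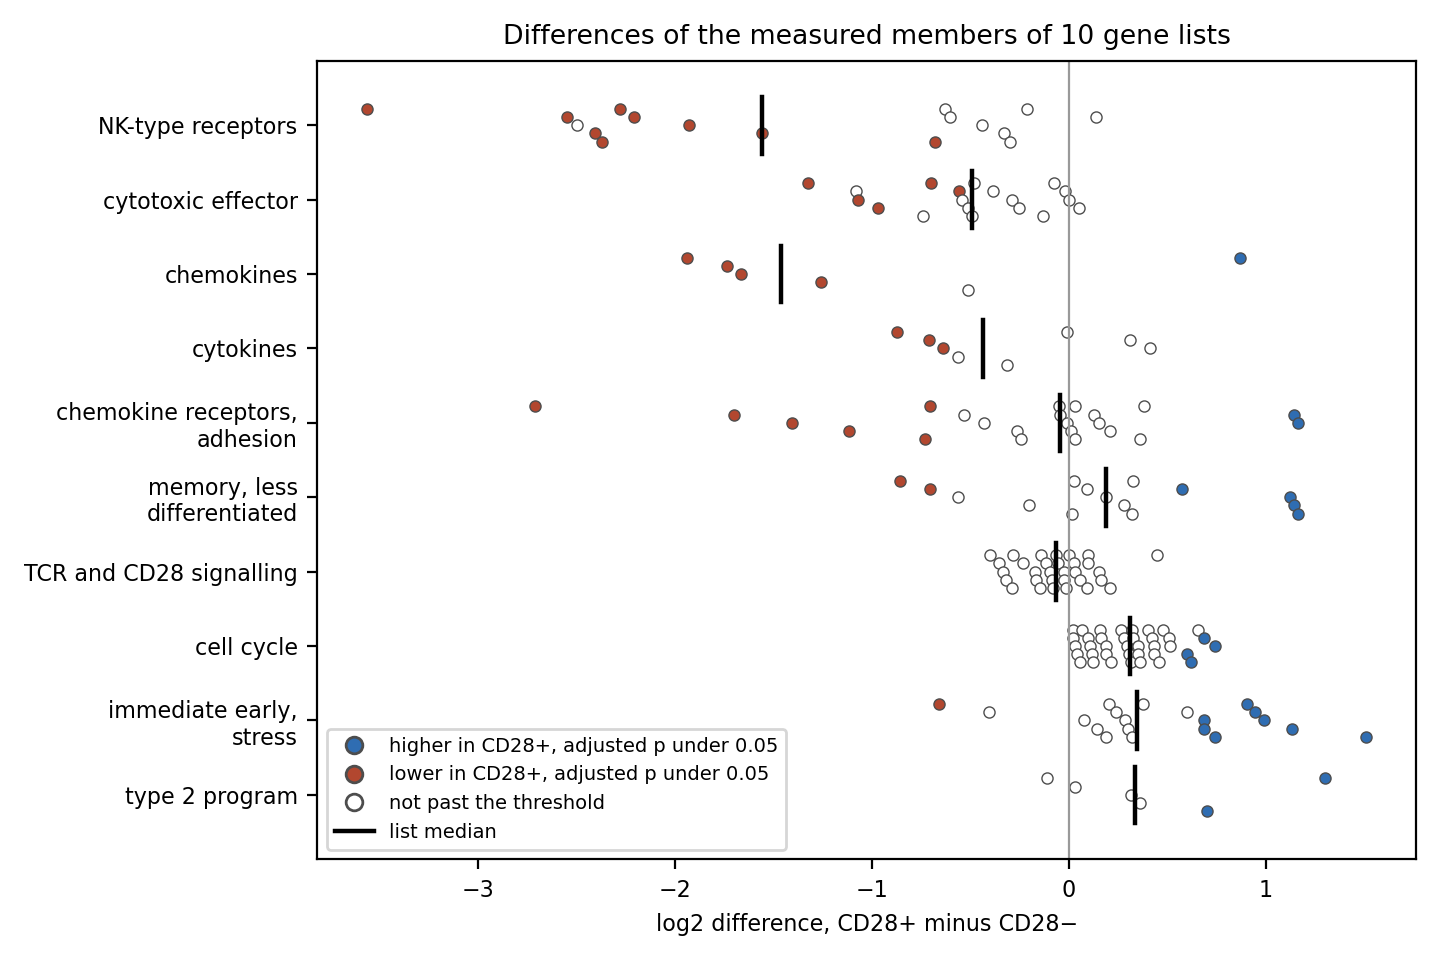
Log2 difference between CD28+ and CD28- cells (horizontal axis) of each measured member of 10 gene lists (vertical axis), 1 probe per gene. Filled points passed a limma adjusted p of 0.05 over all probes and open points did not; the black bar is the list median, at -1.56 for natural killer type receptors, -0.49 for cytotoxic effector genes and 0.31 for the cell cycle. Vertical offsets within a list only separate the points.

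The lists of costimulatory, inhibitory and cytokine receptors did not pass with camera, though single genes did with limma. That leaves a smaller shift of a list possible. Among the costimulatory genes 9 had an unadjusted limma p under 0.05, 7 higher and 2 lower. Of 19 costimulatory receptors and ligands, TNFRSF25 (0.79, limma adjusted p = 0.0107) and TNFRSF8, or CD30 (0.60, limma adjusted p = 0.0490), rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.254). TNFSF14 differed by -0.52 (limma adjusted p = 0.0731), while its 2 other tested probes passed, at -0.82 and -0.67. Of 16 inhibitory receptors and exhaustion genes, PDCD1, which encodes PD-1, rose (0.87, SE 0.15, limma adjusted p = 0.0121) and CD244 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.290). CTLA4 differed by 0.39 on its brightest probe (limma adjusted p = 0.149), and its other probes passed at 0.76 and 0.65. Of 19 cytokine receptors, IL7R rose, and IL9R (-0.71, limma adjusted p = 0.0126) and IL18RAP (-0.64, limma adjusted p = 0.0223) fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.254).

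Of the 6 measured genes of a type 2 program, IL17RB, the interleukin-25 receptor (1.30, SE 0.20, limma adjusted p = 0.00533), and MAF (0.70, limma adjusted p = 0.0140) rose and none fell, with 4 rising when adjusted over the list alone (camera adjusted p = 0.00687; adjusted p = 0.425 with an estimated correlation). GATA3, the factor that defines the program, differed by 0.31 (limma adjusted p = 0.239). MAF was also the only 1 of 7 type 17 genes to pass (2 rose adjusted over the list alone; camera adjusted p = 0.250, with a pass in 1 of 21 other settings). Of 9 genes of HLA class II antigen presentation none passed (limma), 3 had an unadjusted p under 0.05, 3 rose when adjusted over the list alone, and the list was shifted upward (camera adjusted p = 0.0340; adjusted p = 0.502 with an estimated correlation; adjusted p = 0.0709 without the replicate block). HLA-DOA differed by 0.50 (limma adjusted p = 0.0754) and HLA-DPA1 by 0.42 (limma adjusted p = 0.106).

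In several groups few or no genes passed. None of 31 measured genes of T cell receptor and CD28 signalling passed (limma; 7 at an unadjusted p under 0.05; none adjusted over the list alone; camera adjusted p = 0.243), with PIK3CD at -0.36 and CD3G at -0.40. None of 19 glycolysis genes (camera adjusted p = 0.254), 24 oxidative phosphorylation genes (camera adjusted p = 0.385) or 19 senescence and telomere genes (camera adjusted p = 0.340) passed in limma, and 1, 0 and 3 of them had an unadjusted p under 0.05. Adjusted over the list alone the first 2 of these had none and the last had 2 that fell. CDKN2A, which encodes the senescence marker p16, differed by -0.79 (SE 0.20, limma adjusted p = 0.0562). Of 19 interferon response genes only RSAD2 passed; it was not detected on any CD28+ array and was at least 1.93-fold lower there (limma adjusted p = 9.91e-05; 1 fell adjusted over the list alone; camera adjusted p = 0.385). Of 23 apoptosis and survival genes PMAIP1, a BH3-only protein, rose (1.09, SE 0.13, limma adjusted p = 0.00142) and FASLG fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.794). Of 29 ribosomal protein genes RPL37 rose (0.77, limma adjusted p = 0.00889; 1 adjusted over the list alone; camera adjusted p = 0.254).

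Markers of other cell types were mostly near or below background. None of the 6 measured CD8 T cell markers passed (limma; 1 at an unadjusted p under 0.05; none adjusted over the list alone; camera adjusted p = 0.254). Of 4 measured natural killer cell markers 3 fell (3 adjusted over the list alone), namely NCAM1, KLRC1 and KIR2DL4, which are also in the receptor list (camera adjusted p = 4.34e-07; adjusted p = 0.379 with an estimated correlation). Of 5 CD4 and regulatory T cell markers ANKRD55 rose (0.87, limma adjusted p = 0.0121; 2 adjusted over the list alone; camera adjusted p = 0.0415; adjusted p = 0.430 with an estimated correlation; adjusted p = 0.197 without the replicate block). Of 3 fibroblast and endothelial markers PECAM1 (-0.93, limma adjusted p = 0.00390) and PDGFRB (-0.75, limma adjusted p = 0.0287) fell (2 adjusted over the list alone; camera adjusted p = 0.0469; adjusted p = 0.425 with an estimated correlation; adjusted p = 0.0781 without the replicate block). PECAM1 is also made by lymphocytes, and PDGFRB was detected on 2 of the 3 CD28+ arrays. None of 4 monocyte and macrophage markers passed (limma; 0 at an unadjusted p under 0.05; none adjusted over the list alone; camera adjusted p = 0.325), CD68 at 0.26. Lists with under 3 measured members had no set test and no member that passed, whether over all probes, adjusted over the list alone or unadjusted: CD79B (0.32) and MZB1 (-0.28) of B and plasma cells, BATF3 (0.14) of dendritic cells and MITF (0.20) of melanocytes. No gamma-delta T cell or erythrocyte and platelet marker was measured.

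Of 27 lists tested, 11 passed at the preset correlation of 0.01 (camera, Benjamini-Hochberg), 7 without the replicate block, and none with an estimated correlation (3 at an unadjusted p under 0.05), a version that rests on the 2 residual degrees of freedom of this design. A self-contained test (fry) called 2 lists, type 2 (adjusted p = 0.0426) and natural killer cell (adjusted p = 0.0293), while its test for change in either direction called 23.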

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

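The versions of the natural killer receptor list without KIR genes and of the chemokine list without copies, and the count of probes moving the same way in all 3 lines (476 of 476), were chosen after the data were seen; the rest were planned. The comparison was paired by line. With no replicate block, 10 probes passed (3 higher, 7 lower), all 10 among the 476, and 7 lists; the spread between lines then enters the error. With the line as a random block 245 probes passed (115 higher, 130 lower), 244 of them among the 476. With no filter on detection 40 passed (20 higher, 20 lower). With an intensity trend and robust prior 752 passed, 412 of them higher, and with the authors' values 161 of 323 were higher; the cause was not tested for these 3 settings. Leave-outs gave 15 to 608 probes (4 to 328 higher, 11 to 280 lower) and 7 to 13 lists, the lowest probe count without the CD28- array of line 3 and the next, 34, without the CD28+ array of line 3. These fits have fewer samples, and those without 1 array also took the line as a random block, which alone gave 245 probes. Against that 245, the fits without 1 array of line 1 or line 2 gave 148 to 171 probes. Those without the CD28+ or CD28- array of line 3 gave 34 and 15. The drop below 245 goes with the missing array, which also leaves its line unpaired. The 608 without line 1 is no sign of stronger calls, as given above. The remaining settings gave 352 (median scaling) to 682 (no background correction) probes. With median scaling 350 of its 352 probes were among the 476. Estimated correlations called 0 lists, fry 2 and the mean over probes 11. CD28 passed in every setting that tested it, at 2.03 to 3.96; requiring detection on all 6 arrays left it untested. Of 2 other tested CD8A probes, 1 reversed to 0.0347, within its error. The cytotoxic effector, natural killer receptor, chemokine, type 2, cell cycle and immediate early lists passed in 21 of 21 other settings of the fit. The cytokine list passed in 11, HLA class II in 13, CD4 and regulatory T cells in 10, and fibroblast and endothelium in 5 of 20. All of these settings kept the preset correlation of 0.01, and they include the fit without line 1. The chemokine list did not pass once its near-identical copies were left out (camera adjusted p = 0.347). The 118 named genes include some, such as CD8A, that had not passed in the main fit and had no call to lose. The genes outside the counts below are therefore not all genes that kept a call. Of the 118, 89 lost their call without the block and 36 with the line as a random block. With no filter on detection 78 lost it, and with the authors' values 20. Without line 1, 2 or 3, 9, 32 and 30 lost it. Without 1 array and with the line as a random block, 52 to 87 lost it (most without the CD28- array of line 3). No named gene changed direction apart from that CD8A probe. Of the lists, the costimulatory list kept its direction in 18 of 21 other settings and the apoptosis list in 16 of 21. Neither of these lists passed in any of them. The slide as a block was not run, since no slide is named. Signal over background limits dim genes: between 11246 and 12606 of 48803 probes were detected on an array.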

Other observations

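The gene families in this part, and all tests except the counts over other splits, were chosen after the results were seen. The GIMAP genes, small GTPases of lymphocytes that lie next to each other in the genome, were lower in CD28+ cells as a family. All 7 measured members fell, from -0.57 (GIMAP2) to -1.05 (GIMAP6), with GIMAP6 at 9.41 in CD28+ and 10.45 in CD28- cells (SE 0.14, limma adjusted p = 0.00222, n = 3). The other tested probe of GIMAP2 (-0.56, limma adjusted p = 0.107) did not pass. Of 9 protein-coding genes between the ends of the cluster, 8 belong to the family. The family median stayed between -0.90 and -0.78 under the scalings tried, though 4 of 7 passed with median scaling and 3 of 7 with the authors' values. Members of the BEX and TCEAL family, small proteins, went the other way: 4 of 9 rose and none fell, BEX2 by 1.70, BEX3 by 1.33, TCEAL9 by 1.11 and TCEAL3 by 1.06 on the log2 scale. Their genes lie on 1 chromosome but less closely, with 12 of 25 protein-coding genes between the ends in the family. The family median was 0.86, and 7 of 9 were higher under each scaling.

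Of 5 measured keratins, filament proteins of epithelium and hair, 3 fell, singled out here after their values were seen and with no test as a group. Besides KRT86, KRT81 was not detected on any CD28+ array and was at least 1.73-fold lower there (limma adjusted p = 0.00127), and KRT7 differed by -0.95 (limma adjusted p = 0.00752). KRT10 (0.09, limma adjusted p = 0.818) and KRT23 (-0.03, limma adjusted p = 0.963) did not pass. KRT86, KRT81 and KRT7 passed under each scaling. Of 28 measured genes known to be induced by low oxygen, a list written after 6 of them had drawn attention, those 6 rose in CD28+ cells and none fell (limma, Benjamini-Hochberg), with a median of 0.18 over the 28. The 6 were PFKFB4 (1.08), HILPDA (0.89), ADM (0.87), BNIP3 (0.80), VEGFA (0.65) and ANKRD37 (0.64). Others differed little, such as LDHA (0.02) and PGK1 (0.08), or were lower without passing, such as SLC2A1 (-0.17) and EGLN3 (-0.25).

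For the 476 probes that passed, 10 splits of the 6 arrays into 3 and 3 are possible, and 1, the real one, gave as many; the highest of the others was 0. Among the 4 splits that part all 3 pairs the highest other was also 0, and without the block the real split gave 10 and the highest other 2. For gene lists the real split gave 11 and 1 of the 10 splits gave as many, with 8 the highest other and 5 the highest among those that part all pairs. Other splits mix subsets within lines, so the difference between the subsets enters their error. Low probe counts follow from that, and the 0 is no separate support for the 476. List calls at the preset correlation still arise in these splits. With 10 splits no share can go under 0.05.

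The fall of natural killer type receptors in CD28+ cells has as a candidate explanation natural killer cells in the CD28- gate, since the design text describes a gate on cells lacking CD4 with no CD8 stain. The list of natural killer cell markers fixed beforehand had 13 genes, of which NCAM1, KLRC1 and KIR2DL4 were higher in CD28- cells. Of 8 others in it, picked later as less often made by activated T cells (TYROBP, FCER1G, NCR1, SH2D1B, FCGR3A, SYK, SPON2 and KLRF1), 0 were detected on all 3 CD28- arrays and 7 on none. Only 4 of the 13 genes had been tested, and a gene detected on all 3 CD28- arrays would have been among them. All 8 were among the untested genes and were picked after the results were seen, so their count cannot decide the question. Signal shared between probes of near-identical KIR genes may inflate the count of KIR members, but list members outside the family had a median of -0.618 and 4 of 12 fell, so it is not the whole cause. That the T cells of the CD28- subset themselves express these receptors remains a hypothesis, and which KIR genes they express stays open.

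The rise of immediate early genes in CD28+ cells may come from the anti-CD28 antibody of the sort. Of 11 measured genes induced by T cell activation, 0 passed as higher (limma; 2 at an unadjusted p under 0.05) and 4 as lower, with a median of -0.313 and quartiles of -0.648 and 0.107. The bounds of this test were set after its values were known. As the antibody bound 1 subset only, and cytokine genes among the 11 are effector genes that could differ between the subsets anyway, staining and subset cannot be told apart. A single line as the source is argued against, since the list median was higher in CD28+ cells in 3 of 3 TIL lines. A paired fit itself favours such agreement, so it is no separate support for the rise.

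The low-oxygen genes could reflect a hypoxia-type program in CD28+ cells. Both subsets of a line shared 1 culture until the sort, but the sorted subsets then rested for some hours before RNA was taken. In the 22 other measured genes of that list the median was 0.0727 (SE 0.0596), and 16 were higher (camera p = 0.0477; p = 0.337 with an estimated correlation). These 22 are the ones that did not pass, which pulls their median toward 0, so the value says little either way and the hypothesis stays open.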
